A study of Mus musculus with 16 samples.

How the data were processed

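Tail DNA of 8 mice of the C57BL/6 strain was compared with tail DNA of a single reference male of the same colony by comparative genomic hybridization, in which differently dyed DNA of a test animal and of a reference compete for the same probes. The animals were a male parent, a female parent and 6 progeny, per the labels. Each mouse was hybridised on 2 arrays, once in Cy3 and once in Cy5 with the reference in the other dye, which made 16 arrays. The series title names male mice given gamma rays at 1 mGy per day for 400 days, whereas the design text describes the male of this family as not irradiated. The exposure of the male parent was therefore left open, and no comparison was made by dose.

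The deposited scanner tables were written by Feature Extraction 10.7.1.1 with its CGH protocol, per the file headers, and place the probes on mouse genome build mm9. The processed signals are intensity values that, per the file headers, were background-subtracted, spatially detrended and scaled by 1 linear factor per channel, with no lowess term. The deposited log ratio is the log10 of Cy5 over Cy3 of those signals, per the file headers. Raw spot and background medians are unnormalized intensity values in the same deposited files. The series matrix of the authors holds log2 ratios. Set against the scanner ratios, all 16 of its columns ran as reference over mouse, with correlations of at least 0.989 in size and column medians from -0.00555 to 0.015. The small correction that separates it from the scanner ratio, and whether its columns were centred, are not given in the sources used here. Steps between the DNA and the scan other than extraction and labelling are likewise not given in the sources used here.

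Each array held 973116 features, of which 966371 were probes rather than controls. Spots of one probe were averaged. Of 950749 distinct probes, 36 on unplaced contigs were left out and 950713 were used, with a median spacing of 2053 bp, among them 68 on X and 23 on Y. Every ratio was turned to log2 of mouse over reference by the dyes in the labels and centred on the array's autosomal median, with no loess or quantile step. The 2 arrays of a mouse come from the same DNA, so their mean made 1 profile per mouse. There is therefore 1 measurement per animal, standard errors within a mouse run over probes only, and values over progeny are given as mean and SD (n = 6).

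Intervals of 3 to 500 neighbouring probes were searched for the highest score, the summed log2 ratio divided by the robust noise and the square root of the number of probes. A call needed a score of at least 6, a mean and a median beyond 0.3, and a mean beyond 0.2 with the same sign in each dye orientation. Neighbouring calls of one sign were joined, and X and Y were first centred on their own medians. Noise calls were counted in a dye-difference profile of each mouse. This is the halved difference of its 2 orientations after the mean dye bias over the 8 mice was removed. It carries no copy number of the mouse, and it also cancels any error that both arrays of a mouse share. A dye bias of a mouse that departs from that mean stays in it, although it cancels in the averaged profile. The planned noise counts were made without the rule on both orientations and are therefore generous: without that rule the mice had 328 calls against 233. As a check chosen after the data were seen, the rule was also applied to the 2 orientations that make up this profile, with the mean dye bias put back into each as in the arrays, which gave 171. Overlapping calls of one sign were merged into regions. A change of progeny against both parents was a call of one sign in both the difference from the male parent and the difference from the female parent. Counts per mouse were compared by an exact permutation test, two-sided. A region was also set against 10000 random autosomal windows of the same number of probes, less those that crossed a chromosome end or touched a called region of 10 or more probes.

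The search was tested on simulated data: in Gaussian noise of the size of the male parent's profile it made 0 calls over 950713 probes and recovered all 200 planted events. This checks the search but not the rate of false calls on these arrays. The male parent's dye-difference profile gave 24 calls, or 15 under the rule on both orientations. Gains and losses of the size of the female parent's X shift, or halfway to it, were also planted into the dye-difference profiles, and were searched without and with that rule. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0. The normexp alternative, a background correction by a model of signal plus noise, used limma 3.58.1 in R 4.3.3 with an offset of 50, on spot medians because spot means were not used here.

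Before the data were examined, the tests, the calling rule, 59 alternatives and the rule for naming regions were fixed. The alternatives covered the signal, centring, series matrix, probe minimum, size and score limits, dye rule, single orientations, dim probes, a running median over 501 probes, noise per probe, the definition of sharing and of a new change, and, for the shared regions and the differences from both parents, leaving out each of the progeny. The named regions are the 10 largest changes against both parents, the regions called in a parent and some progeny, and the regions called in all 8 mice; other regions were chosen after their values were seen. The scanner files give probe positions without gene symbols, and an annotation of build mm9 was not used here. Regions are therefore given by coordinates, and the planned gene groups and named genes were not analysed here. The denser follow-up arrays and quantitative PCR assays that the design text mentions were also not analysed here.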

Results

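The copy number of the genome was profiled in 1 family of C57BL/6 mice, consisting of a male parent, a female parent and 6 progeny, each against the same reference male on 2 arrays with exchanged dyes. The series asks whether copy number changes appear in the offspring of male mice kept under continuous low-dose-rate gamma rays. Its title and its design text differ on whether the male of this family was irradiated, and no unexposed family was analysed here.

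Between 99.03% and 99.97% of the probe spots of an array were well above background in both channels, and 0 spots were saturated. The noise between neighbouring probes ranged from 0.162 to 0.242 on the log2 scale, and both arrays of progeny 3 were the noisiest of the 16, at 0.235 and 0.242. Averaging both orientations lowered the noise to between 0.0966 in progeny 2 and 0.148 in progeny 3. Over autosomal probes the 2 orientations of a mouse correlated at -0.131 to -0.309 after both were turned to mouse over reference. Arrays of the same orientation from different mice all correlated positively, at 0.145 or higher. The dye-swap means of the 2 parents correlated at 0.21, against -0.0854 to 0.067 in the other 27 pairs. The parents were scanned on one day and the progeny on 4 other days, so that scan day and generation cannot be told apart.

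No whole autosome was gained or lost in any of the 8 mice. The medians of the 19 autosomes lay between -0.0052 and 0.011 in all of them, within the limit of 0.2. On X, the female parent stood at 0.94 and the male parent at -0.03. On Y, the female parent stood at -2.04 and the male parent at 0.07. The 6 progeny lay at 0.01 ± 0.01 on X (mean ± SD, n = 6) and 0.03 ± 0.03 on Y, close to the reference male. The X shift of the female parent gives the measured size of 2 copies against 1 on these arrays, and its sign in both orientations (0.95 and 0.89) matches the dyes in the labels.

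The clearest difference from the reference was a gain on chromosome 4 from 101110482 to 101270535 (74 probes, 160 kb, mm9), which was present in all 8 mice at visibly different heights. The male parent stood at 0.96 ± 0.02 (SE over probes) and the female parent at 0.57 ± 0.01. Among the progeny, replicates 1 and 6 stood at 0.95 and 0.97, and replicates 2, 3, 4 and 5 at 0.55, 0.51, 0.56 and 0.55. The mean of the progeny was 0.68 ± 0.22 (SD, n = 6), which covers both heights. In none of the 8 mice did a random window of 74 probes reach the observed value, and the largest of them was 0.16 (0.22 in another draw).

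A second gain lay on chromosome 14 from 26696789 to 26953407 (65 probes, 257 kb, with 63 of the probes within the first 136 kb). It was called in progeny 1, 2, 3, 5 and 6, at 0.30, 0.30, 0.29, 0.31 and 0.31, whereas progeny 4 stood at -0.01. The female parent had the same height, 0.30 ± 0.01, but just missed the call, and the male parent stood at 0.02 ± 0.01. When a mean beyond 0.2 defined a carrier, the female parent joined and the region counted as shared by a parent and 5 of the progeny, in place of progeny only. Values with the mouse in Cy3 were lower than with the mouse in Cy5 in all 8 mice, for example 0.24 and 0.36 in the female parent. With another background correction, normexp, no mouse was called here, and with the mouse in Cy3 only 1 of the 5 progeny was. The heights with normexp were 0.36 ± 0.01 in the female parent, 0.31, 0.31, 0.25, 0.26 and 0.32 in progeny 1, 2, 3, 5 and 6 and -0.0033 in progeny 4 (SE over probes 0.01 in each). With the mouse in Cy3 the raised mice then stood at 0.07 to 0.19, under the limit of 0.2 for each orientation. Both gains are drawn probe by probe in the plot of the shared gains.

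**Figure D1:**
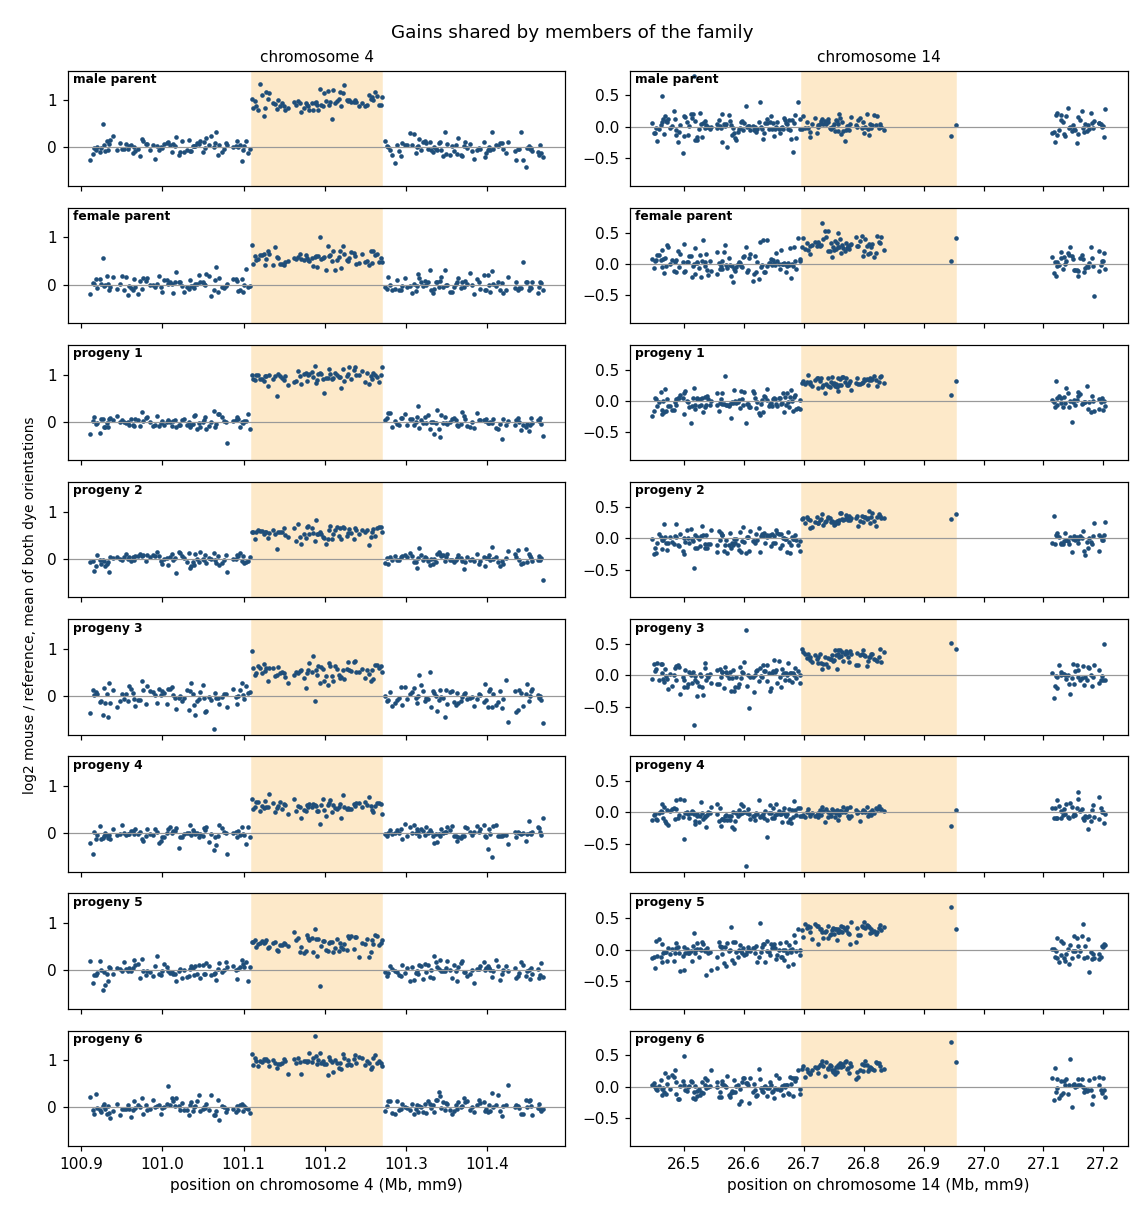
Log2 ratio of mouse over reference (vertical axis, mean of both dye orientations) against position in Mb on chromosomes 4 and 14, with 1 point per probe, 1 panel row per mouse and the called region shaded. On chromosome 4 the male parent and progeny 1 and 6 sit near 0.96 and the other mice near 0.55; on chromosome 14 the female parent and 5 progeny sit near 0.30 while the male parent and progeny 4 sit near 0.

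A loss on chromosome 14 from 53415714 to 54384591 (104 probes, 969 kb) was the only region called in a parent and in some progeny. The male parent stood at -0.30 and the female parent at -0.24, and the progeny averaged -0.23 ± 0.02 (SD, n = 6). Calls were made in both parents and in progeny 1, 2, 3 and 5, covering the whole stretch in the male parent and parts of it in the others. Progeny 4 and 6 had no call, although their means over the region, -0.27 and -0.21, were like those of the called progeny (-0.24 to -0.21). All 8 mice thus lay below the reference, and with normexp all 8 had a call within the region. Part of the stretch is thinly covered, and 19 of its probes were dim or flagged on at least 1 array. In the male parent alone the lowering went on beyond this region. A further 28 probes from 54653290 to 54705309 stood at -0.30 ± 0.03 in that animal, against 0.03 in the female parent and -0.01 ± 0.02 in the progeny (SD, n = 6). With normexp this value was -0.20 ± 0.02 and was not called.

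The female parent carried the deepest autosomal loss of its profile on chromosome 3 from 25417435 to 25432738 (3 probes). The mean was -1.69 ± 0.33 (SE over probes), with -1.88 when the mouse was in Cy3 and -1.50 when it was in Cy5. The male parent had -0.10 there, and the 6 progeny -0.02 ± 0.04 (SD, n = 6). On chromosome 8 the same animal had a gain from 102218986 to 102244157 (10 probes) at 0.30 ± 0.06, which was 0.02 in the male parent and -0.01 ± 0.02 in the progeny. With a size limit of 0.2 the chromosome 8 gain widened to 39 probes from 102132083, at 0.29 ± 0.03 in the female parent and between -0.02 and 0.04 in the progeny. These intervals were chosen after their values were seen.

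**Figure D2:**
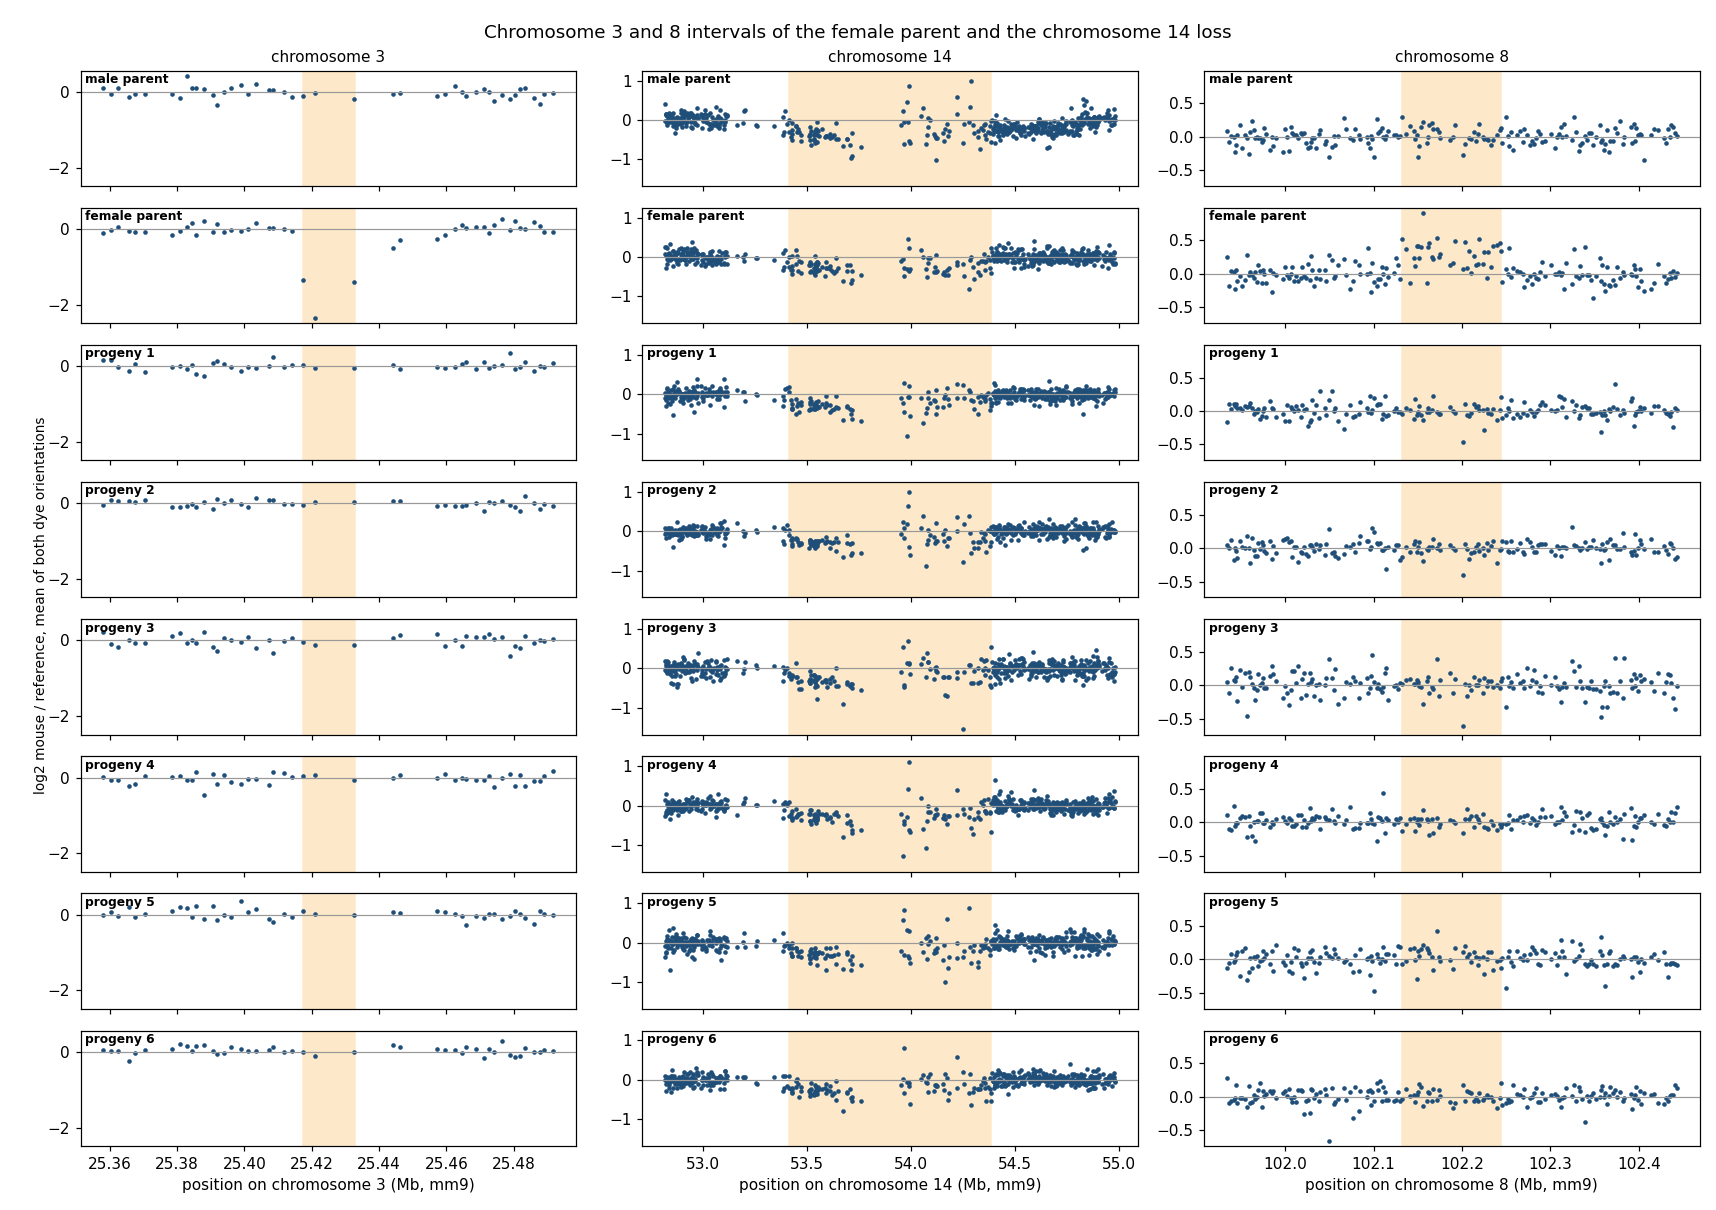
Log2 ratio of mouse over reference (vertical axis, mean of both dye orientations) against position in Mb on chromosomes 3, 14 and 8, with 1 point per probe, 1 panel row per mouse and the region shaded (on chromosome 8, the 39 probes found with the size limit of 0.2). The chromosome 3 loss at -1.69 and the chromosome 8 gain at 0.29 appear in the female parent alone, and the chromosome 14 region lies below 0 in all 8 mice.

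Across the genome, 260 intervals were called in the 8 mice, of which 196 had only 3 probes. The dye-difference profiles, which hold no signal of the mouse, gave 233, or 171 when held to the same rule on both orientations. Of these noise calls 8 had 5 or more probes (6 under that rule), against 35 of the calls in the mice. Those 35 lay in 18 regions, as the shared regions count again in each mouse. Of the 18, 3 were called in several mice and 15, among them a stretch on Y in the female parent, in 1 mouse. Calls numbered 32 in the male parent, 24 in the female parent, and 33, 13, 80, 20, 36 and 22 in progeny 1 to 6, and the corresponding noise counts were 24, 10, 16, 20, 79, 25, 31 and 28. Under the rule on both orientations the noise counts were 15, 6, 10, 14, 60, 18, 25 and 23. In the female parent 4 of the calls lay on Y, where its median was -2.04. Gains made up 48 of the 56 calls in the parents, and losses 150 of the 204 in the progeny. Without the rule on both orientations, gains were 55 of 64 calls in the parents and losses 182 of 264 in the progeny. The noise calls without that rule held 15 gains of 34 in the parents and 116 losses of 199 in the progeny. A majority of losses in the progeny was thus also present in noise. The share of gains in parents and progeny was 80% and 30.2% without dim or flagged probes, 64.7% and 21.3% with a size limit of 0.5, and 85.5% and 28.5% with the running median subtracted. For the mouse in Cy3 only it was 72.2% and 57.1%, so that gains were then the majority in the progeny too. For the mouse in Cy5 only it was 73.6% and 19.4%. A score of 8 gave 50% and 36.6%, and at least 5 probes 61.9% and 40.5%. With noise per probe it was 35.7% and 35.3%, and with at least 10 probes 42.9% of 7 calls and 84.6% of 13. Those 13 all lay in the chromosome 4 gain and the chromosome 14 gain and loss described above, counted once per mouse. They therefore show no direction of calls in the progeny. With normexp few calls were left, with 4 gains of 13 calls in the parents and 8 of 17 in the progeny. Of these, 4 and 13 lay in regions called in 3 or more mice and 4 in the parents on X or Y, so that the 5 and 4 others are too few to show a split. The progeny had 34 ± 24.1 calls per mouse (SD, n = 6) and the 2 parents 28 on average, a difference of 6 that an exact permutation test, two-sided, did not separate from chance (p = 1); with 28 splits the smallest possible p is 0.0714.

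**Figure D3:**
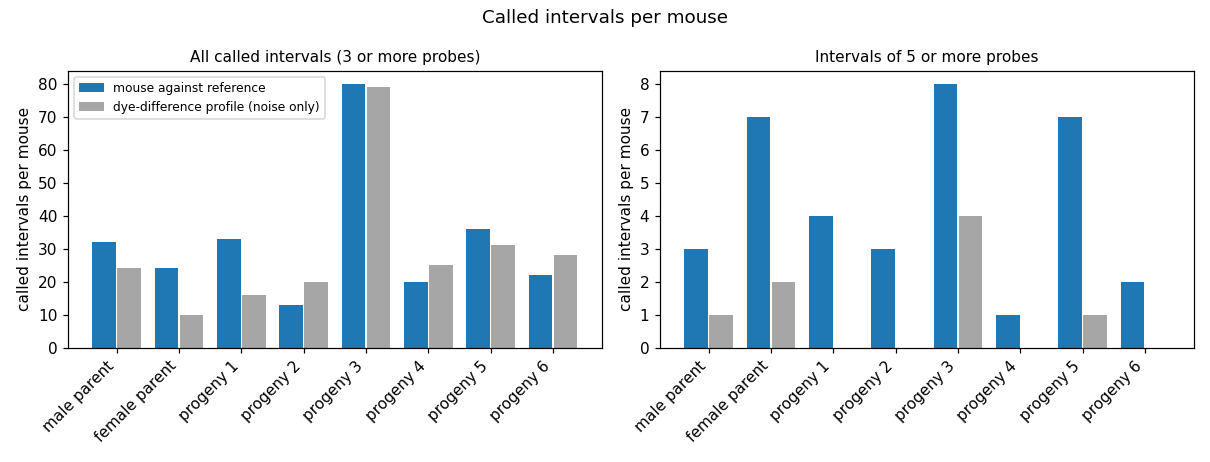
Number of called intervals per mouse (vertical axis, linear from 0) in the profile against the reference (blue) and in the dye-difference profile of the same mouse, which holds no copy number of the mouse and is not held to the rule on both orientations (grey), for all calls and for those of 5 or more probes. Progeny 3 has the most calls (80) and the most noise calls (79), and over the 8 mice calls of 5 or more probes number 35 against 8. The 35 lie in 18 regions, 15 of them called in 1 mouse.

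The calls merged into 240 regions, of which 234 were called in a single mouse. Regions called only in progeny numbered 186, regions called only in a parent 52, and 1 region each was called in all 8 mice (chromosome 4) and in a parent and some progeny (chromosome 14 from 53415714). Of the 6 regions called in more than 1 mouse, 3 are described above. The others were losses of 3 or 4 probes. One on chromosome 4 from 30864431 to 30877356 was called in progeny 1 and 2. A second on chromosome 4, from 139223770 to 139228330, and one on chromosome 18, from 54136033 to 54143691, were called in progeny 1 and 3. Each of these contained at least 1 dim or flagged probe, as did 195 of the 240 regions, although such probes made up 1.75% of the array.

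Progeny differed from both parents in 47 intervals that met the rule, 43 losses and 4 gains. The dye-difference profiles gave 38, 23 losses and 15 gains. Held to the same rule on both orientations, noise gave 27, 18 losses and 9 gains; without that rule the mice had 54 against 38. Progeny 1 to 6 had 7, 5, 21, 2, 5 and 7, against noise counts of 4, 0, 22, 3, 6 and 3. Under the rule on both orientations the noise counts were 2, 0, 15, 3, 4 and 3. Intervals of 5 or more probes numbered 4, against 6 from noise (4 under that rule). With the search itself set to at least 5 probes there were 6, against 2 (1 under that rule). The longest was a loss in progeny 1 on chromosome 11 from 49968047 to 49990362 (11 probes), at -0.34 from the male parent and -0.36 from the female parent. Progeny 1 had -0.18 there against the reference and the parents 0.16 and 0.15. In 0 of the 47 intervals did both parents carry an opposite call, but in 42 of them the progeny lay below parents that were both above 0, and only 24 were also called against the reference. On chromosome 17 from 75129297 (progeny 2) the male parent itself had a called gain, at 0.56. The female parent stood at 0.48 there and progeny 2 at -0.11. The median over the 47 intervals was 0.22 in the male parent and 0.18 in the female parent, whose profiles correlated with each other as described above. Of the 47, 43 held a dim or flagged probe.

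The 10 largest of these differences comprised 9 losses and 1 gain, each of 3 or 4 probes, and 8 of them were in progeny 3. The largest was a loss in progeny 3 on chromosome 1 from 166797872 to 166801299, at -1.41 from the male parent and -1.33 from the female parent. Against the reference this loss stood at -2.08 with the mouse in Cy3 but -0.38 with the mouse in Cy5, with a median of -0.75. Losses in the same animal followed on chromosome 7 from 95598958 to 95603468 (-1.08 and -0.93), on chromosome 1 from 128423459 to 128427319 (-0.84 and -0.90), and on chromosome 2 from 118966735 to 118970103 (-0.97 and -0.75). The gain was in progeny 2 on chromosome 7 from 66229137 to 66245833, at 0.89 and 0.82. Progeny 3 also had losses on chromosome 11 from 37620331 to 37625885 (-0.87 and -0.84) and from 21333688 to 21349786 (-0.86 and -0.84). Progeny 1 had a loss on chromosome 17 from 56704932 to 56708457 (-0.80 and -0.89). The remaining 2 were losses in progeny 3, on chromosome 6 from 52777579 to 52781429 (-0.77 and -0.88) and on chromosome 10 from 12188369 to 12192458 (-0.75 and -0.89). Each of the 10 contained a dim or flagged probe. Among all 47, 3 positions recurred in different progeny, on chromosome 1 from 188545401 (progeny 1, 3 and 6), on chromosome 7 from 63966192 (progeny 1 and 3) and on chromosome 7 from 66229137 (progeny 2 and 6). The male and female parents stood at 0.35 and 0.31, 0.36 and 0.22, and -0.23 and -0.16 there. All progeny were set against these same parents, so the recurrences are not independent. Only progeny 1 was also called against the reference, at the first and second position.

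Planted events show what size of change a search of 1 profile could reveal, with the 8 mice pooled. Recovery in progeny 3, the noisiest, was not given apart. The rule on differences from both parents, which also carry the noise of the parent profiles, was not tested in this way. Of events as large as the X shift (0.94), 94 of 94 gains and 102 of 102 losses of 3 probes were recovered, with exact binomial 95% lower bounds of 96.2% and 96.4%. Of events halfway to it (0.47), 80.6% of gains and 79.6% of losses of 3 probes were recovered, 96.8% and 97.1% of those of 5 probes, and all of those of 10 or 20 probes. These shares leave out the rule on both orientations. With that rule applied, 77.4% of gains and 76.7% of losses of 3 probes and 95.7% and 96.1% of those of 5 probes were recovered at 0.47, and all of those of 10 or 20 probes or of size 0.94. These intervals cover counting error only. A gain of 3 copies against 2, which would lie at 0.55 on the scale of the X shift, was not planted. Changes covering fewer than 3 probes, whose median spacing was 2053 bp, could not be called, and regions without probes were not measured.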

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

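The tests of noise, dim probes, dye, scan day, copy changes and copy steps below were chosen after the results were seen, except the test of the chromosome 3 loss against the dye-difference profile. A single mouse far from the other 5 progeny was looked for in 33 sets of values, and 12 sets contained one, where chance gives about 1 in 20. Most of those sets were intervals picked because 1 mouse stood apart, so that their number carries no weight.

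Progeny 3 had 80 called intervals against 13 to 36 in the other progeny, and 21 differences from both parents against 2 to 7. Held to the same rule on both orientations, its dye-difference profile gave 60 calls, against at most 25 in the other progeny. It led the progeny with the next most calls by 44 calls and by 35 noise calls (exact binomial p = 0.000187 for the noise calls). That p treats intervals as independent and covers counting error in single profiles, not the spread between arrays or animals. Progeny 3 was also picked as the extreme of the progeny. The excess of calls over noise in progeny 3 was 20, within the -1 to 23 of the other progeny. The lead in noise calls and this excess argue against copy changes of this animal as the whole source of the lead. Array noise is a likely source of most of the lead under the main rule. Of the 60 noise calls, 56 held a dim or flagged probe, and the other 4 were no more than in other progeny (at most 7). Such probes were those dim or flagged on at least 1 array of any mouse. The arrays of progeny 3 had the lowest shares of spots well above background, 99.06% and 99.03%. Calls of this animal were therefore likely to meet such probes, and only 10 of its 80 calls held none. The share thus does not set noise at dim probes apart in progeny 3. The noise calls did not cover all of its calls, however, and in 5 of 13 settings its excess lay above that of all other progeny. Such an excess can also hold errors that both arrays of a mouse share, since the dye-difference profile cancels them. Noise calls can in turn hold a dye bias particular to the mouse, which cancels in the averaged profile. With a size limit of 0.5 progeny 3 had 30 calls against 16 from noise, an excess of 14 (1 to 4 in the other progeny). With a score of 5 it had 240 against 174, an excess of 66 (4 to 38), and with dim and flagged probes left out 16 against 6, an excess of 10 (-1 to 7). With noise per probe, estimated from the same noise profiles, it had 12 against 0 (an excess of 3 to 7 in the others). Calls found with at least 5 probes numbered 20 against 9, an excess of 11 (2 to 9); these last counts are too few to set noise and copy changes apart. A true change among its calls stays open.

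On chromosome 14 from 26696789, progeny 4 stood at -0.0051 while the other progeny ranged from 0.29 to 0.31. This step and those on chromosome 4 exceeded the random windows drawn, of which the largest of 65 probes was 0.10. Another draw in the male parent reached 0.23 for 68 probes and 0.22 for 74 probes, still below the raised levels. The search had picked these regions as extremes, so the windows alone cannot exclude noise. The same heights recurred in several mice, however. Scan day does not account for the steps, since progeny 1 and 2, scanned together, differed on chromosome 4 by 0.40 ± 0.02 (SE over probes) and the parents, also scanned together, differed by -0.28 (male minus female) on chromosome 14. On the scale of the X shift, 3 and 4 copies against 2 would lie at 0.55 and 0.94, and the 8 mice fell within 0.043 of 1 of these levels on chromosome 4. With normexp and its own X shift of 0.85 the largest distance was 0.0996 (progeny 3, 0.40 against 0.50), just inside the limit of 0.1, and each of the 8 mice was nearer to the same number of copies as before. Inheritance of 4 copies in the male parent, 3 in the female parent and 4 in 2 of the progeny is therefore a candidate explanation. On chromosome 14 the nearest raised mouse lay 0.24 from the level of 3 copies against 2, while 5 against 4 would give 0.30; the number of copies in the reference stays open.

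Single mice also stood apart in shorter intervals. Progeny 3 had 0.43 on chromosome 1 from 141639483, -0.41 on chromosome 11 from 9674209, 0.40 on chromosome 11 from 118485155 and -0.46 on chromosome 12 from 120258196. Progeny 5 had 0.34 on chromosome 7 from 114767497. Random windows of the same length in the same mouse reached larger values for 3 of these: 0.44 for chromosome 11 from 118485155, 0.51 for chromosome 12 and 0.38 for chromosome 7, 1 window in about 10000 each. For chromosome 1 and for chromosome 11 from 9674209 the largest was 0.32 and 0.33. All of these intervals were found as extremes by a search of the whole profile, so few random windows could reach them even in noise. The windows therefore cannot exclude noise. In progeny 3, calls of 5 or more probes numbered 8, against 4 from noise under the rule on both orientations. Among the largest differences from both parents, progeny 3 had -1.23 on chromosome 1 from 166797872, -0.78 on chromosome 7 from 95598958, -0.69 on chromosome 11 from 37620331 and -0.70 on chromosome 10 from 12188369, all against the reference. Those on chromosomes 1, 11 and 10 were uneven between the orientations, as given above.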

How the results depend on the processing

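Leaving out each of the progeny was planned for the shared regions and the differences from both parents. Chosen after the data were seen were leaving out progeny 3 from the call counts, the rule on both orientations for noise, and most alternatives for the difference in calls of progeny and parents. No paired analysis was possible, as each parent is a single animal. The gene group alternatives were not run, as probes were not named. The cause of each change below was not tested unless stated.

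The 260 calls became 30 with normexp, 63 with at least 5 probes, 20 with at least 10, 411 with a size limit of 0.2, 64 with 0.5, 763 with a score of 5, 53 with a score of 8, 391 in Cy5 only, 73 without dim or flagged probes and 48 with noise per probe. Noise calls held to the same rule on both orientations changed from 171 to 4, 16, 0, 305, 24, 491, 27, 31 and 0 (Cy5 only aside), the last with noise per probe taken from these profiles. The rule took the 233 noise calls to 171, the 38 noise differences from both parents to 27, and the recovery of 3-probe events halfway to the X shift from 80.1% to 77%. Without progeny 3 there were 180 calls against 111 from noise under the rule.

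The 6 regions called in more than 1 mouse became 2 with normexp, 3 with at least 5 or 10 probes, 10 with a size limit of 0.2, 3 with 0.5, 14 with a score of 5, 3 with a score of 8, 19 in Cy5 only, 12 in Cy3 only, 3 without dim or flagged probes, and 89 when a mean beyond 0.2 made a carrier. Leaving out each of the progeny gave 3 (without progeny 1) to 6. The chromosome 4 gain was called in all 8 mice in each of these settings. The chromosome 14 gain from 26696789 was called in 0 mice with normexp or a size limit of 0.5 and in 1 in Cy3 only, and the loss from 54653290 in none with normexp, in Cy5 only, with a size limit of 0.5 or with the running median.

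The 47 differences from both parents became 1 with normexp, 6 with at least 5 probes, 1 with at least 10, 71 with a size limit of 0.2, 22 with 0.5, 198 with a score of 5, 5 with a score of 8, 94 in Cy3 only, 8 without dim or flagged probes and 1 with noise per probe. Noise under the dye rule gave 2, 1, 1, 45, 7, 124, 3, 1 and 0 in these settings (Cy3 only aside). The differences became 302 against the mean of both parents and 193 when a call in progeny and none in a parent sufficed, because these rules ask less. Leaving out each of the progeny gave 26 (without progeny 3, against 12 from noise) to 45. Of the 47 intervals, 1 was found again with noise per probe (chromosome 8 from 127582545, progeny 3), 0 with normexp and 4 without dim or flagged probes.

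The difference in calls of progeny and parents, 6, turned to -3.5 with at least 5 probes and -0.667 with a size limit of 0.5 (exact permutation p = 0.643 and 0.571), both planned. Among the alternatives chosen later it turned to -3.67 with normexp, -1.33 with at least 10 probes, -4.17 with a score of 5, -1.17 without dim or flagged probes, -1.33 with noise per probe and -3.2 without progeny 3 (p = 0.357, 0.214, 0.714, 0.786, 0.643 and 0.762). Elsewhere it stayed positive, up to 28.2 in Cy3 only (p = 0.143), so that it has no settled direction. No autosome was called under any alternative tried for whole chromosomes. The X shift of the female parent ranged from 0.85 with normexp to 0.95 in Cy3 only. Of 336 recomputed values of 6 described regions in single mice, 270 stayed within their 95% error over probes, 66 moved beyond it and 0 changed sign where called. Signal over background was lowest in progeny 3; its effect on short intervals was not compared between mice.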

Other observations

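With the size limit lowered to 0.2, 26 calls of 10 or more probes were made, all on autosomes, against 2 in the dye-difference profiles (0 under the rule on both orientations), and they fell into 7 regions. Apart from those described above, these were single-mouse losses: in progeny 3 on chromosome 3 from 83984924 to 84007078 (12 probes, -0.26) and on chromosome 6 from 64295499 to 64323338 (14 probes, -0.30), and in progeny 4 on chromosome 13 from 48955336 to 48972675 (10 probes, -0.20). The largest random window of the same length in the same mouse was 0.28, 0.21 and 0.20. Thus 1 of 9995 windows was larger than the chromosome 3 loss and none was larger than the other losses. The search had picked these losses as extremes of the whole profile, so few random windows could reach them even in noise. The windows therefore cannot exclude noise for these losses. The parents stood at 0.05 and 0.09, -0.03 and 0.00, and 0.14 and 0.10 in these intervals (male and female). The chromosome 14 loss then ran as one stretch of 291 probes from 53415714 to 54806857, with -0.25 in the male parent and between -0.09 and -0.07 in the other mice. The genes of the T-cell receptor alpha and delta chains, which T cells rearrange by deleting DNA, lie on chromosome 14 in the mouse; whether this stretch holds them was not analysed here.

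The loss on chromosome 3 in the female parent, at -1.69, was deeper than the X shift of 0.94 that 2 copies against 1 gave. An artefact of a single dye is argued against by -1.50 in the weaker orientation. Noise of 3 probes is argued against by the dye-difference profile of the same mouse, in which no 3 neighbouring probes exceeded 0.57. Loss of both copies in the germ line would have lowered all 6 progeny, the lowest of which stood at -0.093. What remains open may be a change confined to the sampled tail tissue or a fault of that DNA sample, which a single sample per animal cannot separate.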
